A study of Mus musculus with 22 samples.

How the data were processed

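Messenger RNA from 22 mouse libraries (11 groups of 2) was analysed. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was enriched with oligo(dT) beads and sheared, libraries were made with a KAPA mRNA-seq kit, and they were sequenced in paired ends on a HiSeq 2000. The strain was C57BL/6 per the labels. Groups were taken from the labels: induction cultures of mouse embryonic fibroblasts on 7 days from day 1 to day 21, primary neurosphere-like clusters (pre-NPC), the established line at passage 6 (giNPC P6), progenitors from neonatal brain (Brain-NPC) and teratoma. The factors used for induction, the origin of the teratoma and whether the 2 libraries of a group were separate inductions are not given in the sources used here.

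The authors deposited a count table and an FPKM table for each library. The deposited counts are whole-number read counts per RefSeq transcript, ending in HTSeq's summary lines per the file headers and contents, and HTSeq 0.6.0 is named in the submitters' processing notes. The deposited FPKM values (fragments scaled to transcript length and library size) are Cufflinks transcript tables per the file headers, and Cufflinks 2.2.1 is named in the submitters' processing notes. The same notes name TopHat2 2.0.12 for alignment, the mm9 genome and edgeR. What the authors ran in edgeR, and the strand setting of the counting, are not given in the sources used here. Positions are printed in mm9, as the FPKM tables give them.

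Between 20.86% and 27.09% of the reads in a count table fell in transcripts, which is 3084428 to 9689996 per library, and 48.02% to 56.31% had no feature. The tables list 29243 transcripts, which were summed by gene name into 23600 genes, 22517 of them with a gene symbol. Because counting was per transcript, reads shared by overlapping transcripts of a gene were set aside as ambiguous. This was tested on the tables by setting the counts against those expected from FPKM and length: of 2753 genes with several transcripts and at least 1000 expected counts, 2562 had under 0.5 of them, against 342 of 9675 genes with 1 transcript. For named genes under 0.5 the text prints FPKM, except where CPM is stated. Of the 14339 genes tested on counts, 1257 have several transcripts and 1008 lie under 0.5. FPKM tables were used for 15831 genes with an FPKM of at least 1 in at least 2 libraries.

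Counts were normalised by TMM and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test, after filterByExpr, in 1 fit of all 22 libraries with a mean per group. With 2 libraries per group this leaves 11 residual degrees of freedom shared by all groups, and the common biological coefficient of variation was 0.161. These tests were two-sided. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05 with at least a 2-fold change. Transiently high genes at a stage had to be higher than both day 1 and giNPC P6, with the larger of both one-sided p-values adjusted over genes (an intersection-union test) and at least a 2-fold change in each. FPKM values were tested with limma 3.58.1 on log2(FPKM + 1). Similarity was measured by Spearman correlation of log2 CPM across tested genes, and by principal components of the 2000 most variable genes. Figures show the values per library.

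The comparisons were days 4 to 21 with day 1, pre-NPC with day 21, giNPC P6 with pre-NPC, with Brain-NPC and with day 1, teratoma with giNPC P6, and the number of genes that differ from Brain-NPC at day 1, day 21 and in pre-NPC. The comparisons, tests, thresholds, gene lists, rule for named genes and the first set of other settings below were fixed before the data were examined.

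A set of 31 gene lists was tested with limma's camera at a preset correlation of 0.01, adjusted over all 403 pairs of list and comparison. The lists were fibroblast, smooth muscle and contractile, epithelial, pluripotency, early reprogramming, neural progenitor, forebrain regional, midbrain and hindbrain regional, Hox, neuron, astrocyte, oligodendrocyte lineage, neural crest, endoderm, mesoderm and muscle, cartilage and bone, surface ectoderm, endothelial, immune, erythroid, germ cell, proliferation, p53 and senescence, interferon response, imprinted, DNA methylation enzymes, glycolysis, immediate early and stress, BMP, TGF-beta and inhibitors, candidate induction factors, and sex chromosome. Camera was repeated with an estimated correlation, and fry tested each list on its own. The number of called members is given over all genes tested and adjusted over the list alone, where only the list's members enter the adjustment. Overlap of lists with transient genes was tested by Fisher's exact test, one-sided, against all tested genes. That test takes genes as independent, so its p-values are too small for lists whose members vary together.

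Genes named per main comparison were: the 5 highest and 5 lowest log2 fold changes among called genes with at least 10 CPM in the higher group and no overlap between libraries; up to 4 called members of each list that was called or had at least 1 in 3 of its members called in 1 direction, those with the smallest adjusted p; 33 anchor genes followed whatever their values; and, for transient genes, the 10 with the largest change in pre-NPC and 5 at each other stage. Symbols ending in Rik or starting with Gm and a number were left out of the highest and lowest genes. Genes of the lists and anchors may be left unnamed, and a few genes met by these rules are not reported here; the totals over named genes leave them out. The further genes of the day 4 to day 17 comparisons, of the overlap with lists and of the other observations were chosen after their values were seen.

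Depth sets what a low value means. A group with no counts for a gene is given a floor of 3 counts over its 2 libraries together, which corresponds to 0.149 CPM in teratoma and 0.463 CPM at day 21. Folds against such a group are lower bounds, ratios against 1 to 3 counts have exact 95% intervals, and list medians are also given with such genes at their bound. The intervals count reads, so they cover counting error only.

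The tests were checked on simulated counts drawn with the overall mean and estimated dispersion of each gene and the library sizes of these data, with 200 genes changed in giNPC P6 and 200 others raised in pre-NPC. For giNPC P6 against Brain-NPC over 13073 genes edgeR recovered 80 of 100 genes changed 3-fold and 87 of 100 changed 6-fold, with 7 false calls, and for transient genes in pre-NPC it recovered 77 and 95 of 100. DESeq2 recovered 81 and 85 with 8 false calls for giNPC P6 against Brain-NPC. Limma on log2 values recovered 78 and 88 of 100 over 13838 genes with 6 false calls. Each simulated gene had the same dispersion in all groups. In the data the chi-square per degree of freedom between replicates was 29.94 in giNPC P6 and 2.16 in Brain-NPC. The simulation does not cover that difference in spread. Camera called 2 of 200 random lists at an unadjusted p under 0.05. The simulated genes varied independently, so this check does not cover lists whose members vary together.

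Other settings fixed beforehand were RLE size factors, a stricter filter (CPM of at least 1 in at least 2 libraries), no filter, DESeq2 1.42.0, a block for the replicate number, no teratoma libraries, only the groups of a comparison, no fold minimum, log2(FPKM + 1) with and without a filter, log2(FPKM + 0.1), and leaving out each of the 22 libraries in turn. Chosen after seeing the data were tests of only genes with 1 transcript, of transient genes without those that follow the immune list (Pearson r of at least 0.8 over the libraries), and camera on log2(FPKM + 1). With 2 libraries per group no regrouping of the samples was tested. Reads that were not unique, ambiguous or without a feature were not used here, nor were the FPKM confidence limits, and genes failing the filters were left out of the tests.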

Results

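Gene expression was measured by sequencing of poly(A)-selected RNA in 22 mouse libraries, 2 for each of 11 groups. Induction cultures started from mouse embryonic fibroblasts were sampled at days 1, 4, 7, 10, 14, 17 and 21. The pre-NPC group held primary neurosphere-like clusters from the induction, and the giNPC P6 group held an established line of induced neural progenitor cells at passage 6. Brain-NPC, neural progenitors grown from neonatal brain, was the reference for authentic progenitors, and the last group was teratoma tissue whose source the labels do not give. Each library had 3084428 to 9689996 reads counted in transcripts, and 12926 to 17127 genes had at least 1 count, with the highest numbers in teratoma.

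Values below are TMM-normalised CPM (counts scaled to library size), given as mean ± SD of the 2 libraries of a group. Log2 fold changes are given with an approximate standard error. On counts this error is the log2 fold change divided by the square root of the test's F. It was not estimated separately, and it can fall below counting error for genes with few reads in a group. A gene was called higher or lower at an adjusted p under 0.05 and a change of at least 2-fold in edgeR's quasi-likelihood test. The deposited counts lose most reads of genes with several transcripts, so for 11 such genes named below (Pax6, Il1rl1, Spp1, Map2, Meg3, Grb10, Mbp, Xist, Bcan, Sall4 and Esrrb) the FPKM and limma's test on log2(FPKM + 1) are given instead, except where CPM is stated. A fold against a group with no counts is a lower bound against 3 counts over its 2 libraries together, and a ratio against 1 to 3 counts has its 95% interval. These intervals and bounds cover counting error only. A log2 fold change printed for a gene with no counts in 1 group is a fitted value that can far exceed the bound. Such values serve only to compare settings. P-values measure only the spread between these libraries, since the labels do not say whether the 2 libraries of a group came from separate inductions. That spread was estimated for each gene over all groups together. For groups whose replicates differ more than those of other groups, such as day 4 and giNPC P6 (below), p-values can therefore be too small.

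Replicates resembled each other unevenly. Spearman's rho across genes between the 2 libraries of a group ranged from 0.974 in giNPC P6 to 0.995 in teratoma. The spread beyond counting noise was largest at day 4 and in giNPC P6, where the chi-square per degree of freedom was 29.16 and 29.94, against 2.16 in Brain-NPC and 3.32 at day 1. In giNPC P6 the replicates differed in Olig2 (428 ± 367 CPM), Lhx2 (65.6 ± 52.7) and Hoxa9 (88.1 ± 87.7), and in sex-linked genes. Xist had 643 CPM in giNPC P6 replicate 1 and 22.4 in replicate 2, while Eif2s3y, on the Y chromosome, had 0 and 93.0 CPM.

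The overall profile of the cultures was compared with Brain-NPC to place each stage between fibroblasts and neural progenitors. Spearman's rho with Brain-NPC was 0.740 at day 1, fell to 0.704 at day 4, and reached 0.811 at day 10, 0.889 at day 14 and 0.905 at day 17. It was 0.885 in pre-NPC, 0.942 in giNPC P6 and 0.718 in teratoma. On log2(FPKM + 1) rho with Brain-NPC was 0.725 at day 1, 0.68 at day 4, 0.939 in giNPC P6 and 0.671 in teratoma. The lowest value was thus at day 4 on counts and in teratoma on FPKM. These correlations are across genes, which are not independent replicates, and describe the profiles without a test. In a principal component analysis of 2000 genes, component 1 held 58.2% of the variance and component 2 held 22.56%.

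**Figure D1:**
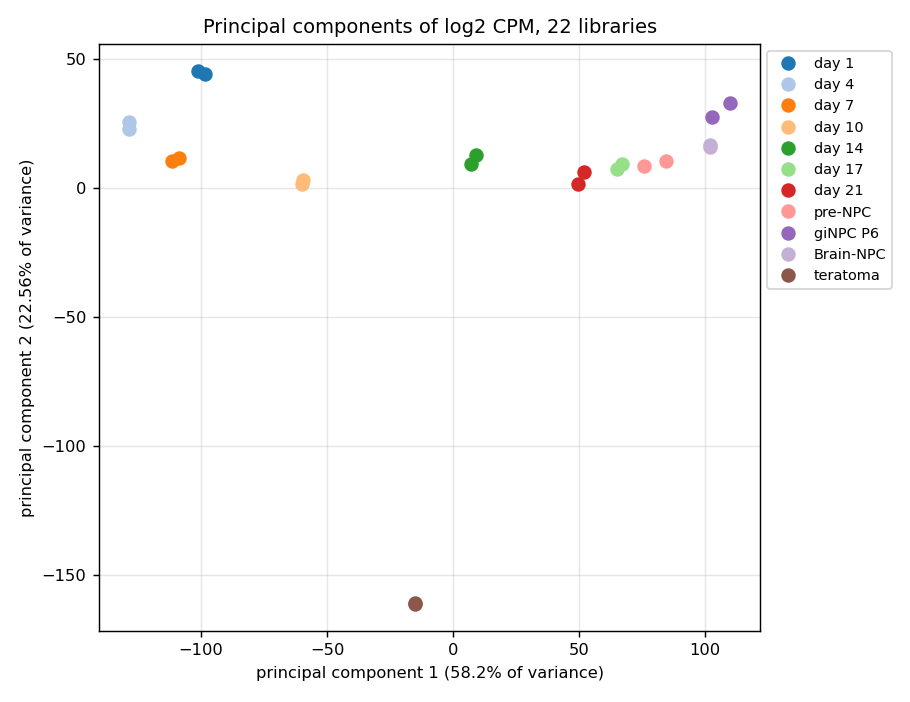
Principal components 1 and 2 of log2 CPM over 2000 genes, with 1 point per library and the percent of variance on each axis. On component 1 day 1 lies at -101.03 and -98.32, day 4 at -128.48 and -128.38, day 17 at 65.19 and 66.85, day 21 at 51.96 and 49.71, and giNPC P6 at 102.83 and 109.94, while teratoma lies apart on component 2.

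Days 4 to 21 were compared with day 1 to follow how fibroblast expression gave way to neural expression. Sox2, a transcription factor of neural progenitors on chromosome 3 (34548927 to 34551382, mm9), rose from 1.24 ± 0.396 CPM at day 1 to 19.9 ± 2.27 at day 7 (log2 fold change 4.01 ± 0.29, adjusted p = 1.15e-09), 158 ± 7.71 at day 10 and 600 ± 79.4 at day 21 (8.92 ± 0.24, adjusted p = 6.21e-17). The factors used for induction are not given in the sources used here, so reads of an introduced copy of Sox2 cannot be told from reads of the gene itself. Olig2 rose from 0.312 ± 0.171 to 49.8 and 31.4 CPM in the day 7 libraries and peaked at 1110 ± 18.9 at day 14. Pax6 rose from 0.0159 FPKM at day 1 to 13.9 ± 0.18 at day 10 and 24.9 ± 0.268 at day 21. Nes, which encodes the intermediate filament nestin, was already at 301 ± 22.8 CPM at day 1. It fell to 102 ± 7.45 at day 4 and stood at 388 ± 14.6 at day 21, under 2-fold from day 1. Of the fibroblast genes, Thy1 went from 861 ± 8.56 CPM at day 1 to 332 ± 20.5 at day 7 and 35.3 ± 5.44 at day 14, and Col1a1, the main collagen I chain, from 4630 ± 142 to 1440 ± 76.7 and 388 ± 9.51.

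Between these movements, macrophage and interferon-response genes were high from day 4 to day 10. Ifit1, Oasl2, Csf1r, Lyz2 and Emr1 were chosen here after their values were seen. Ifit1, an antiviral gene induced by interferon, rose from 18.6 ± 1.92 CPM at day 1 to 523 ± 141 at day 4 (4.82 ± 0.26, adjusted p = 6.4e-11), and Oasl2 from 20.3 ± 0.521 to 444 ± 1.29 (4.45 ± 0.15, adjusted p = 1.21e-14). Csf1r, the receptor for the macrophage growth factor, rose from 98.4 and 103 CPM in the day 1 libraries to 1020 ± 389 at day 4 and was 947 ± 4.81 at day 7. Lyz2, the macrophage lysozyme, reached 21800 ± 592 CPM at day 7 against 1480 ± 59.1 at day 1. Emr1, which encodes the macrophage marker F4/80, was at 1050 ± 13.7 CPM at day 10 and 39.5 ± 5.16 at day 17. By day 14 Csf1r, Lyz2 and Oasl2 were not called against day 1, and by day 21 all 5 genes were lower than at day 1.

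**Figure D2:**
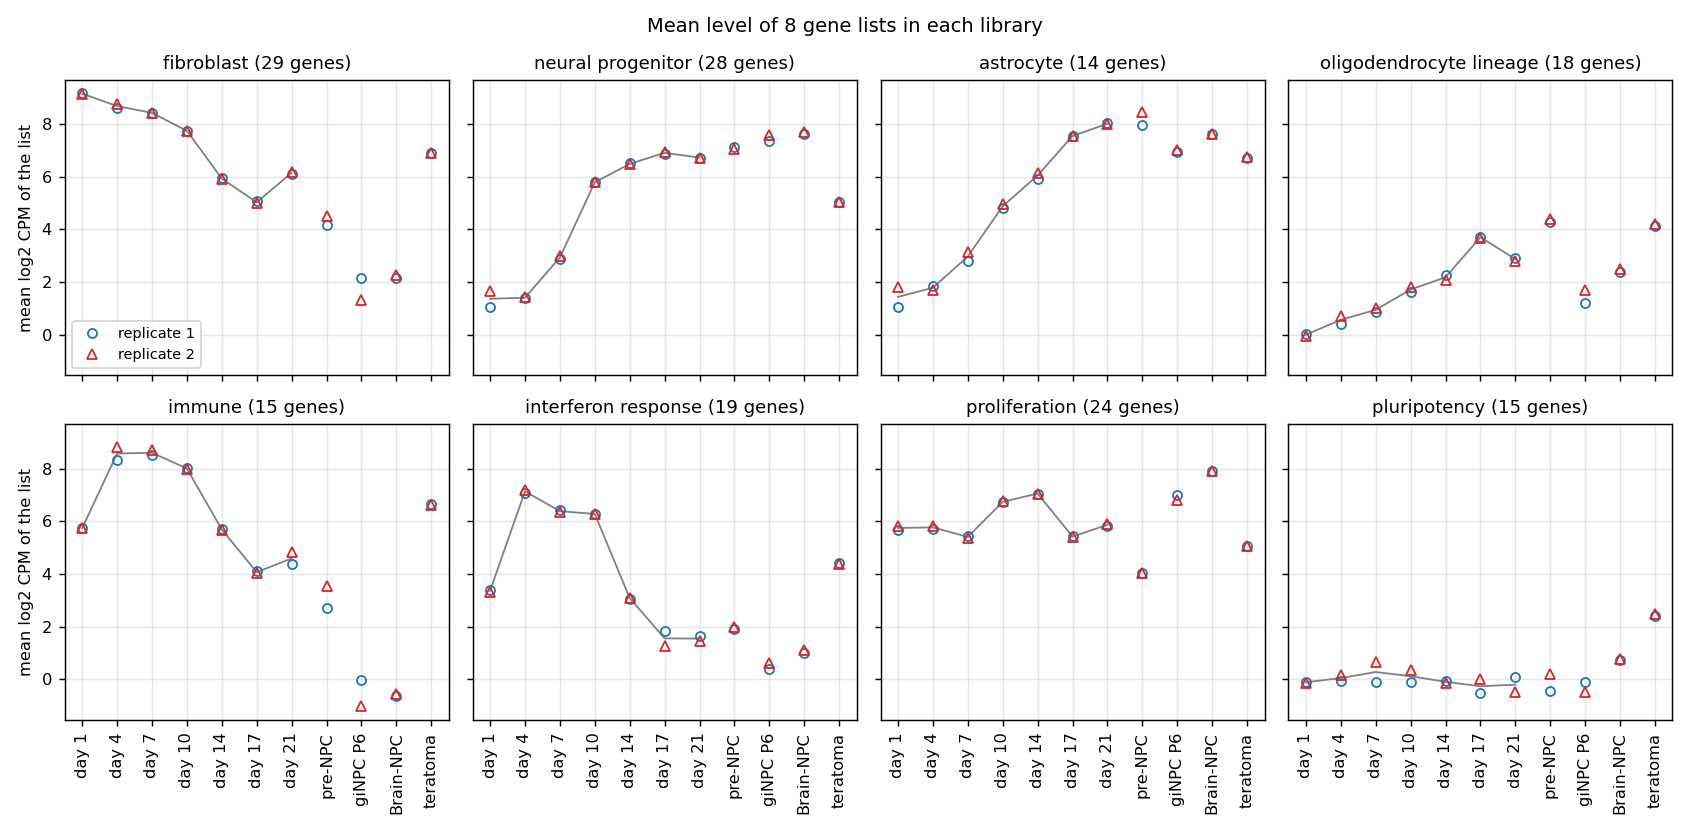
Mean log2 CPM of 8 gene lists in the 11 groups, with the libraries as points. The immune list stands at 8.61 at day 7 and -0.53 in giNPC P6, while the neural progenitor list climbs from 1.36 at day 1 to 7.47 in giNPC P6 and the fibroblast list falls from 9.16 to 1.74.

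In these day comparisons 1209 genes were higher and 266 lower at day 4 than at day 1. The counts were 1670 and 574 at day 7, 2198 and 944 at day 10, 2218 and 1727 at day 14, 2794 and 2452 at day 17, and 2804 and 2293 at day 21. Of the 15 tested immune genes 14 were higher at day 4, 14 at day 7 and 14 at day 10. The list's camera adjusted p of 2.21e-13 at day 4 became 0.0472 with an estimated correlation, while 8.68e-10 at day 7 and 2.44e-06 at day 10 became adjusted p = 0.0945 and 0.196 with an estimated correlation. Of the 19 tested interferon-response genes 18, 17 and 17 were higher on those days (median log2 fold change 4.11 at day 4, adjusted p = 3.7e-22, and 0.000948 with an estimated correlation). Of 28 neural progenitor genes 13 were higher and 3 lower at day 7 (camera adjusted p = 0.000514, and adjusted p = 0.0853 with an estimated correlation), and 22 were higher and 1 lower at day 10 (adjusted p = 6.42e-16, and 0.0029 with an estimated correlation). The fibroblast list had 4 of 29 genes lower at day 4, 13 at day 7, 20 at day 10 and 27 at day 14; its adjusted p values at days 4 and 7 were 0.2 and 0.148 with an estimated correlation. The proliferation list had 14 of 24 genes higher at day 10 and 18 at day 14, among them Mki67, which went from 224 ± 17.0 CPM at day 1 to 649 ± 9.39 at day 14 and back to 174 ± 9.81 at day 17. Adjusted over the list alone 18 interferon genes and 14 neural progenitor genes were higher at day 7, and the other list counts in this paragraph were the same.

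Day 21 was compared with day 1 as the end of the sampled induction. Among the largest rises were those of Mt3, Agt, Mmd2, Timp4 and Lrrc4b. Mt3, the brain metallothionein, had 1240 ± 277 CPM at day 21 and no counts at day 1, at least 4090-fold higher (adjusted p = 2.1e-13). Agt, Mmd2, Timp4 and Lrrc4b likewise had no counts at day 1 and 443, 413, 324 and 241 CPM at day 21, at least 1460-fold, 1350-fold, 1060-fold and 791-fold higher (adjusted p = 2.76e-13, 4.11e-16, 1.02e-13 and 1.04e-13). Slc1a3, a glutamate transporter of radial glia and astrocytes, rose from 2.28 ± 1.06 to 1890 ± 261 CPM (9.70 ± 0.26, adjusted p = 6.21e-17), and Aldoc from 3.59 ± 0.746 to 3110 ± 173 (9.76 ± 0.27, adjusted p = 7.71e-17). Bcan rose by 7.63 ± 0.15 on the log2(FPKM + 1) scale (adjusted p = 1.56e-14). Gfap, the astrocyte filament, was at 1.83 ± 2.32 CPM on day 1 and 2760 ± 138 on day 21, a log2 fold change of 10.61 that was 9.56 without day 1 replicate 1 and 13.60 without day 1 replicate 2.

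Among the largest falls by day 21 were those of Grem1, Spp1, Il1rl1, Gzme and Htr1b. Grem1, a secreted BMP antagonist, had 592 CPM at day 1 and 0.309 at day 21, a ratio of 1920 (interval 531 to 15900, adjusted p = 5.57e-16). Spp1, which encodes osteopontin, went from 26800 ± 107 to 106 ± 9.91 FPKM (-7.97 ± 0.5 on the log2(FPKM + 1) scale, adjusted p = 3.7e-09), and Il1rl1 from 19.2 ± 2.0 to 0.103 ± 0.146 FPKM (-4.20 ± 0.1, adjusted p = 1.58e-13). Gzme and Htr1b had 36.0 and 32.8 CPM at day 1 and no counts at day 21, at least 78-fold and 71.2-fold lower (adjusted p = 2.75e-07 and 1.3e-06). Fn1 fell from 18800 ± 986 to 778 ± 109 CPM (-4.60 ± 0.27, adjusted p = 4.34e-12), as did Ddr2 (-3.92 ± 0.20) and Lum (-3.71 ± 0.20). The latent growth factor gene Tgfb1 fell from 283 ± 3.11 to 18.8 ± 2.44 CPM (-3.91 ± 0.21, adjusted p = 9.27e-13), and the p53 target Mdm2 from 786 ± 22.4 to 132 ± 9.69 (-2.58 ± 0.17, adjusted p = 2.83e-11). Interferon-response genes ended below their day 1 level, with Oasl2 at 3.39 ± 0.11 CPM (-2.57 ± 0.21, adjusted p = 1.61e-09) and Ifit1 at 1.99 ± 0.589 (-3.20 ± 0.43, adjusted p = 1.72e-06).

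Over the fixed gene lists, 24 of 28 neural progenitor genes were higher and 1 was lower at day 21 than at day 1 (median log2 fold change 7.89, or 6.07 with genes at 0 set at their bound; camera adjusted p = 3.23e-13). In the fibroblast list 27 of 29 genes were lower (median -3.00, adjusted p = 1.63e-11), in the astrocyte list 12 of 14 were higher (median 7.69, bound 7.29, adjusted p = 5.34e-08), in the oligodendrocyte lineage list 9 of 18 were higher and 1 lower (median 4.95, bound 4.26, adjusted p = 0.00326), and in the interferon-response list 13 of 19 were lower (median -2.08, bound -1.78, adjusted p = 0.000183). These calls held with an estimated correlation. A further 3 calls did not. Of 32 Hox genes 15 rose and 1 fell (median 1.36, adjusted p = 0.018, and adjusted p = 0.242 with an estimated correlation), with Hoxa7 rising from 10.9 ± 1.1 to 107 ± 4.55 CPM and Hoxa5 from 8.2 ± 1.58 to 112 ± 23.5. Of 15 immune genes 9 fell (median -1.23, adjusted p = 0.0237, and adjusted p = 0.564 with an estimated correlation). Of 18 imprinted genes 8 fell and 1 rose (median -1.27, adjusted p = 0.00745, and adjusted p = 0.139 with an estimated correlation), with Igf2r at -4.50 ± 0.30 and Rian at -4.50 ± 0.30. Adjusted over the list alone the oligodendrocyte count was 10 higher, the interferon count 14 lower and the imprinted count 9 lower, and the other counts in this paragraph were the same.

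The remaining lists passed no camera threshold at day 21. Genes called higher and lower were 4 and 2 of 9 for smooth muscle (adjusted p = 0.737), 7 and 2 of 19 for neurons (0.34), 8 and 8 of 20 for BMP, TGF-beta and inhibitors (0.853), 2 and 7 of 15 for immediate early and stress (0.0618), 1 and 5 of 14 for p53 and senescence (0.161), 1 and 5 of 16 for glycolysis (0.376) and 5 and 2 of 10 for candidate induction factors (0.083). They were 2 and 1 of 24 for proliferation (0.853), 3 and 1 of 16 for forebrain (0.876), 3 and 1 of 12 for midbrain and hindbrain (0.938), 2 and 1 of 9 for neural crest (0.709), 4 and 0 of 8 for cartilage and bone (0.185), 2 and 3 of 14 for mesoderm (0.571), 0 and 3 of 20 for endoderm (0.536) and 1 and 1 of 12 for surface ectoderm (0.737). The endothelial list had 1 and 2 of 10 (0.917), the germ cell list 1 and 2 of 3 (0.853), the DNA methylation list 1 and 0 of 5 (0.895), the sex chromosome list 0 and 2 of 5 (0.675), and none of the 3 erythroid genes was called (0.889). The BMP median was 0.43 with a mean of -0.07, the midbrain and hindbrain median -0.17 with a mean of 0.50, and the DNA methylation median -0.21 with a mean of 0.27. These counts were the same adjusted over the list alone, except for 2 forebrain genes higher.

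Genes of pluripotency and of early reprogramming were followed over the course because the study's title names a partially reprogrammed state. Pou5f1, which encodes Oct4, stayed at or under 0.949 ± 0.704 CPM (day 14) in all groups but teratoma, where it was 2.83 ± 0.348. Nanog, whose counts hold 0.052 of those expected from FPKM, is given as FPKM: it was at 0.277 ± 0.0228 at day 14 and did not exceed 0.436 ± 0.262 (pre-NPC). Lin28a did not exceed 0.151 CPM outside teratoma (7.83 ± 1.71), and Sall4 did not exceed 0.109 FPKM outside teratoma (1.62 ± 0.0437). Zfp42 was highest at day 21 with 0.603 ± 0.853 CPM, and Esrrb was at 0.0517 ± 0.0473 FPKM at day 1, 0.742 ± 0.0596 in giNPC P6 and 0.794 ± 0.0677 in Brain-NPC. Cdh1 and Epcam, epithelial genes that rise early in reprogramming, did not exceed 2.59 ± 0.914 CPM (day 4) and 3.77 ± 0.587 (pre-NPC), against 282 ± 10.8 and 220 ± 5.41 in teratoma. Alpl, the gene for alkaline phosphatase, rose from 0.217 ± 0.307 CPM to 15.0 ± 0.085 at day 10 and 99.2 ± 5.94 at day 21 (ratio to day 1 of 488, interval 135 to 4040, adjusted p = 1.98e-11), and was 84.5 ± 6.85 in Brain-NPC. Fut4, which makes the SSEA-1 epitope, fell from 16.3 ± 1.14 CPM to 0.452 ± 0.639 at day 21 (ratio 35.2 lower, interval 11.8 to 172, adjusted p = 3.07e-05). Fut9, which makes the same epitope and was added after its values were seen, rose from 0.899 ± 0.352 CPM to 83.9 ± 3.60 at day 21 (6.49 ± 0.42, adjusted p = 2.26e-11), 472 ± 23.9 in pre-NPC and 170 ± 29.8 in giNPC P6. Klf4 fell from 73.2 ± 4.69 to 9.28 ± 2.05 CPM (-2.98 ± 0.26, adjusted p = 3.71e-09). At day 21 the pluripotency list had 2 of 15 genes higher and 2 lower (median 0, camera adjusted p = 0.947), the early reprogramming list 4 of 13 higher and 2 lower (adjusted p = 0.423), and the epithelial list 1 of 21 higher and 3 lower (adjusted p = 0.164). The pluripotency counts were 1 and 1 adjusted over the list alone, and the other counts were the same.

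To find genes of passing stages, each stage from day 7 on was searched for genes higher than both day 1 and giNPC P6. At day 7 there were 897 such genes, led by Cd4, Slc6a12, Slfn4, Cd79b and Pydc3, which had 24.8 ± 7.38, 18.0 ± 0.903, 13.7 ± 6.85, 10.9 ± 4.22 and 10.5 ± 1.92 CPM (adjusted p = 1.18e-06, 5.16e-05, 3.72e-05, 8.17e-05 and 5.16e-05). At day 10 there were 637, led by Cd5l (13.3 ± 1.49 CPM), Cd4 (12.9 ± 1.7), Cyp24a1 (18.3 ± 5.17), Cxcl13 (14.9 ± 4.08) and Gbp8 (11.3 ± 0.569). Both sets held leukocyte and interferon genes. Of the 897 genes 421 followed the mean of the immune list over the 22 libraries with a Pearson r of at least 0.8, as did 314 of the 637. That split was chosen after seeing the data, and genes selected for this course tend to follow the list by their selection. The day 7 set held 14 of the 15 immune genes and 17 of the 19 interferon-response genes (Fisher's exact test, one-sided, adjusted p = 8.42e-15 and 4.2e-17). The day 10 set held as many of each. Fisher's test takes genes as independent, so for lists whose members vary together its p-values here and below are too small. At day 14 there were 176, with Marco, a macrophage scavenger receptor, at 582 and 609 CPM in the 2 libraries against 9.59 ± 1.6 at day 1. Cd209f, Cxcl13, Cyp24a1 and Lcn2 were at 11.1 to 13.4 CPM. This set held 1 of the 15 immune genes (Fisher's exact test, one-sided, adjusted p = 0.832) and 3 of the 18 oligodendrocyte lineage genes (0.0186). The day 14 count ranged from 112 without day 1 replicate 1 to 201 without giNPC P6 replicate 2.

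The sets of later stages held glial genes. At day 17 there were 298, led by Neu4, Rec8, Fa2h, Sstr1 and Luzp2 at 15.2 ± 1.83, 11.4 ± 3.76, 20.4 ± 0.393, 19.5 ± 0.432 and 37.4 ± 3.96 CPM. At day 21 there were 353, led by Glycam1 (20.4 ± 3.28 CPM), Gabrb1 (47.2 ± 0.659), Gabra2 (100 ± 8.93), Eef1a2 (13.5 ± 2.84) and Gfap, which was 2760 ± 138 at day 21 and 25.7 ± 5.14 in giNPC P6. In pre-NPC there were 607. Sox10, a master regulator of oligodendrocyte identity, was among those with the largest changes, at 122 ± 23.8 CPM against 0.574 ± 0.812 at day 1 and 1.85 ± 1.23 in giNPC P6 (adjusted p = 7.17e-10). The others were Neu4 (14.8 ± 0.801 CPM), Gabrb1 (44.1 ± 1.95), Fa2h (13.8 ± 3.88), C4b (77.0 ± 56.7), Enpp6 (25.7 ± 21.0), Bmp6 (17.1 ± 4.61), Mag (23.1 ± 6.05), Ip6k3 (15.7 ± 4.88) and Gfap (1500 ± 1280). The pre-NPC set held 11 of the 18 oligodendrocyte lineage genes (among them Gpr17, Mag, Myrf and Sox10; Fisher's exact test, one-sided, adjusted p = 6.47e-10) and 5 of the 14 astrocyte genes (Aldh1l1, Aqp4, Atp1b2, Clu and Gfap, adjusted p = 0.0033). Gpr17, which marks oligodendrocyte precursors about to differentiate, was at 919 ± 48.7 CPM on day 17, 401 ± 118 in pre-NPC and 10.7 ± 11.3 in giNPC P6. The day 17 set held 8 oligodendrocyte genes (adjusted p = 3.6e-08) and 4 astrocyte genes (0.00288), and the day 21 set held 5 (0.00119) and 4 (0.0046). Of these sets 1 gene at day 17, 6 at day 21 and 6 in pre-NPC followed the immune list, against 856 of all 14339 tested genes. The mean log2 CPM of that list was 5.74 at day 1 and 4.07, 4.59 and 3.13 at these stages. Genes selected as higher than day 1 are therefore unlikely to follow it, and the low numbers say little about macrophage genes. The sets hold genes above both day 1 and giNPC P6, so a gene that is high in Brain-NPC can be among them, as Luzp2 was (86.2 ± 3.65 CPM there).

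Pre-NPC was compared with day 21 to see what set the neurosphere-like clusters apart from the last sampled culture. Whether both groups came from the same embryos is not given in the sources used here. Xist was at 384 and 610 CPM in the pre-NPC libraries and at most 1.39 CPM at days 1 to 21. The differences below may thus reflect the source of the cells as well as the stage. Proliferation, smooth muscle and fibroblast genes were lower. Mcm2, a replication licensing factor, fell from 127 ± 10.9 to 21.9 ± 2.95 CPM (-2.54 ± 0.15, adjusted p = 1.55e-10), and Mki67 from 242 ± 12.4 to 95.2 ± 7.52 (-1.35 ± 0.16, adjusted p = 2.4e-06). Acta2, smooth muscle actin, which had risen to 382 ± 31.0 CPM at day 21, was 7.26 ± 2.72 in pre-NPC (-5.71 ± 0.28, adjusted p = 2.19e-11), and Col1a1 fell from 703 ± 89.7 to 66.7 ± 21.9 (-3.40 ± 0.27, adjusted p = 1.2e-08). Nes fell from 388 ± 14.6 to 121 ± 15.4 CPM (-1.68 ± 0.13, adjusted p = 8.37e-09) while Sox1 rose from 8.44 ± 2.56 to 62.6 ± 7.87 (2.88 ± 0.37, adjusted p = 7.52e-06). Among oligodendrocyte genes Sox10 rose from 29.1 ± 4.51 to 122 ± 23.8 CPM (2.07 ± 0.31, adjusted p = 2.73e-05), Gpr17 by 2.41 ± 0.35 and Myrf by 2.68 ± 0.40 on the log2 scale.

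The largest rise in pre-NPC was in Xist, the RNA that silences an X chromosome, at 39.7 ± 13.8 FPKM against 0.0592 ± 0.0361 at day 21 (5.22 ± 0.84 on the log2(FPKM + 1) scale, adjusted p = 0.000165). Tsix, its antisense partner, had 58.7 CPM against no counts, at least 127-fold higher (adjusted p = 0.000939), but the strand setting of the counting is not given in the sources used here, so reads of Xist and Tsix cannot be separated. On log2(FPKM + 1) without a filter the change of Tsix was 0.00. Car9, a hypoxia-induced carbonic anhydrase, was at 63.6 ± 4.64 CPM against 0.301 ± 0.426, a ratio of 206 (interval 56.8 to 1710, adjusted p = 4.75e-06). Sncb and Cyp2j13 had 13.7 and 10.2 CPM against no counts, at least 29.6-fold and 22.1-fold higher (adjusted p = 1.26e-06 and 0.00428), and DESeq2 gave Cyp2j13 an adjusted p of 0.443. Pdk1, which restrains pyruvate oxidation, rose from 22.3 ± 2.11 to 201 ± 55.5 CPM (3.17 ± 0.19, adjusted p = 1.55e-10), and Pfkp from 41.1 ± 2.37 to 228 ± 40.3 (2.47 ± 0.20, adjusted p = 1.5e-08). The genes that fell furthest had no counts in pre-NPC. Nkx6-1, a ventral neural tube factor, was lower by at least 75.1-fold, Ly86 by at least 51.8-fold, Slc38a4 by at least 44.5-fold, Pou3f1 by at least 44-fold and Pgr by at least 36.2-fold (adjusted p = 4.39e-06, 7.14e-08, 7.11e-08, 0.00013 and 1.03e-05). Pgr was under 2-fold on log2(FPKM + 1) without a filter (-0.89). Its fitted log2 fold change on counts, which lies beyond the bound, was -8.27 without day 21 replicate 2.

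In all, 1179 genes were higher and 1332 lower in pre-NPC than at day 21. Of 24 proliferation genes 22 were lower (median log2 fold change -1.84, camera adjusted p = 5.93e-19), as were 8 of 9 smooth muscle genes (median -4.83, adjusted p = 5.34e-08) and 21 of 29 fibroblast genes with 1 higher (median -1.85, adjusted p = 2.33e-08). That 1 gene is Prrx1, whose counts hold only 0.087 of those expected from FPKM. Of 18 oligodendrocyte lineage genes 10 were higher and 1 lower (median 1.90, bound 1.63, adjusted p = 0.0017). These 4 calls held with an estimated correlation, at adjusted p = 0.0013, 0.0029, 0.0428 and 0.0329. Glycolysis genes had 5 of 16 higher (median 0.84, adjusted p = 0.000271, and adjusted p = 0.233 with an estimated correlation). Of 15 immune genes 12 were lower and 1 higher (adjusted p = 0.000542, and adjusted p = 0.36 with an estimated correlation), such as Laptm5, which fell from 75.4 ± 7.15 to 16.6 ± 7.27 CPM. Of 32 Hox genes 12 were lower and 1 higher (adjusted p = 0.00462, and adjusted p = 0.164 with an estimated correlation). The neural progenitor list, with 2 of 28 genes higher and 1 lower, was not called (adjusted p = 0.158), nor was the astrocyte list, with 2 of 14 higher (0.663). Adjusted over the list alone 2 oligodendrocyte genes and 13 Hox genes were lower and 3 neural progenitor genes higher, and the other counts were the same.

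The giNPC P6 line was compared with pre-NPC to list the differences between the clusters and the established line. Whether these groups came from the same embryos as the cultures of days 1 to 21 is not given in the sources used here. Xist had 384 to 643 CPM in 3 of these 4 libraries and 22.4 in giNPC P6 replicate 2, against at most 1.39 CPM at days 1 to 21. Proliferation genes rose and oligodendrocyte lineage genes fell, while the call of the astrocyte list was lost with an estimated correlation (below). Ccna2, cyclin A2, rose from 38.4 ± 2.97 to 297 ± 34.2 CPM (2.95 ± 0.16, adjusted p = 1.96e-11), Mcm2 from 21.9 ± 2.95 to 171 ± 14.5 (2.97 ± 0.15, adjusted p = 9.41e-12) and Plk1 from 8.73 ± 2.19 to 115 ± 14.9 (3.71 ± 0.21, adjusted p = 3.52e-11). Nes rose from 121 ± 15.4 to 579 ± 11.6 CPM (2.25 ± 0.13, adjusted p = 6.49e-11), and Sox2 was not called, at 766 ± 84.5 against 823 ± 54.0 (-0.10 ± 0.14, adjusted p = 0.629). Myrf fell (-4.29 ± 0.43). Of single astrocyte genes Aqp4, a water channel, fell as well (-3.35 ± 0.27). Gfap fell from 1500 ± 1280 to 25.7 ± 5.14 CPM (-5.86 ± 0.48, adjusted p = 6.65e-09), and this change was -6.55 without pre-NPC replicate 1 and -4.53 without pre-NPC replicate 2. Col6a1 fell from 237 ± 39.6 to 7.71 ± 0.499 CPM (-4.93 ± 0.20, adjusted p = 3.99e-13), and Grb10, an imprinted growth regulator, from 50.4 ± 10.1 to 0.486 ± 0.131 FPKM (-5.10 ± 0.13, adjusted p = 1.05e-11).

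The largest rises in giNPC P6 over pre-NPC were in Mybl2, a cell cycle transcription factor (24.3 against 0.397 CPM, 5.86 ± 0.48, adjusted p = 6.2e-09), Car3 (33.0 ± 16.2 against 0.599, 5.74 ± 0.54, adjusted p = 5.7e-08), Fgf13 (ratio 118, interval 20.9 to 4700, adjusted p = 5.88e-07) and Syt9 (17.6 ± 15.8 CPM, ratio 169, interval 30.1 to 6720, adjusted p = 8.44e-06). Pou3f1 returned to 11.1 ± 12.8 CPM from no counts, at least 35.2-fold higher (adjusted p = 0.000159). Without giNPC P6 replicate 1 the fitted log2 fold changes of Syt9 and Pou3f1 went from 7.19 and 9.04 to 5.74 and 6.65. The values of Pou3f1 lie beyond its bound. Mag, Neu4, Luzp2 and Xdh had no counts in giNPC P6. They were at least 103-fold, 66.3-fold, 57.4-fold and 52.9-fold lower (adjusted p = 9.22e-07, 1.04e-05, 5.6e-08 and 6.18e-07). The fitted log2 fold change of Xdh, which lies beyond its bound, was -9.15, and -8.01 without pre-NPC replicate 2. Itih5 fell from 44.9 ± 16.6 to 0.0695 CPM, a ratio of 603 (interval 108 to 23900, adjusted p = 2.73e-11). The forebrain factor Lhx2 was at 65.6 ± 52.7 CPM against 1.89 ± 0.153, with a log2 fold change of 5.10 that was 3.89 without giNPC P6 replicate 1 and 5.75 without replicate 2. Car3 was likewise uneven, at 5.13 without giNPC P6 replicate 1, 4.75 without pre-NPC replicate 1 and 10.63 without pre-NPC replicate 2.

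In all, 1101 genes were higher and 1543 lower in giNPC P6 than in pre-NPC. All 24 tested proliferation genes were higher (median 2.87, camera adjusted p = 4.81e-30). Of 18 oligodendrocyte lineage genes 13 were lower and 1 higher (median -3.09, adjusted p = 3.67e-07), of 29 fibroblast genes 18 were lower (median -3.25, bound -2.52, adjusted p = 1.29e-12), of 19 interferon-response genes 9 (median -1.99, adjusted p = 0.000203) and of 9 smooth muscle genes 5 (adjusted p = 0.00638). These 5 calls held with an estimated correlation, at adjusted p = 0.000665, 0.00455, 0.0152, 0.0431 and 0.0434. Of 15 immune genes 14 were lower (median -4.89, bound -4.53, adjusted p = 7.48e-12, and adjusted p = 0.0635 with an estimated correlation), among them Cd14, from 15.7 ± 1.02 to 0.827 ± 0.187 CPM. Of 16 forebrain genes 4 were higher (adjusted p = 0.0213, and adjusted p = 0.111 with an estimated correlation), and of 14 astrocyte genes 6 were lower (adjusted p = 0.0481, and adjusted p = 0.307 with an estimated correlation). Adjusted over the list alone 15 oligodendrocyte, 19 fibroblast and 6 smooth muscle genes were lower and 1 fibroblast gene was higher, and the other counts were the same. The Hox list, with 6 of 32 genes higher and 4 lower, was not called (adjusted p = 0.876), and its median of 0 went with a mean of -0.28.

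The giNPC P6 line was compared with Brain-NPC to ask how close the induced cells came to progenitors from the brain. Among the anchor genes, Sox2, Fabp7 and Sox1 were not called, while Nes and Olig2 were (below). Sox2 was at 766 ± 84.5 CPM against 624 ± 27.4 (0.30 ± 0.14, adjusted p = 0.111), Fabp7 at 4280 ± 1030 against 3680 ± 89.1 (0.22 ± 0.44, adjusted p = 0.788) and Sox1 at 92.6 ± 26.1 against 72.8 ± 2.02. Regional identity genes differed. Hoxa5, a positional gene of the hindbrain and trunk on chromosome 6 (52151753 to 52154586, mm9), had 111 ± 70.1 CPM in giNPC P6 and no counts in Brain-NPC, at least 496-fold higher (adjusted p = 4.63e-10), and Hoxa9 and Hoxa2 were at least 426-fold and 223-fold higher (adjusted p = 1.18e-07 and 1.35e-08). The fitted log2 fold change of Hoxa9, whose size beyond the bound is not measured, was 12.05. It was 10.27 without giNPC P6 replicate 2 and 12.81 without replicate 1. Without replicate 1 the fitted value of Hoxa5 went from 12.37 to 11.52 and that of Hoxa2 from 11.22 to 10.44. Hoxb2 was steadier between replicates, at 43.6 ± 0.529 CPM and at least 201-fold higher. Msx1, a dorsal and neural crest factor, was at 34.1 ± 8.32 CPM against 1.96 ± 0.199 (4.11 ± 0.38, adjusted p = 6.7e-08), and Irx2 at 60.8 ± 5.66 against 6.17 ± 0.817 (3.30 ± 0.22, adjusted p = 4.63e-10).

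Forebrain genes were the reverse. Six3 had 52.2 ± 3.35 CPM in Brain-NPC against 1.23 ± 0.614. Luzp2, Otx2 and Sp8 had no counts in giNPC P6 and were at least 72-fold lower (adjusted p = 2.9e-10, 1.08e-05 and 2.92e-05). Ttr, made by choroid plexus, had 429 ± 1.22 CPM in Brain-NPC against 0.160, a ratio of 2890 (interval 799 to 23800, adjusted p = 6.16e-11), and Fndc3c1 70.6 against 0.0800 CPM (ratio 948, interval 170 to 37500, adjusted p = 7.11e-08). Nes was lower in giNPC P6 (579 ± 11.6 against 1260 ± 71.5 CPM, -1.12 ± 0.13, adjusted p = 1.05e-06), as was Mcm2 (-1.54 ± 0.13, adjusted p = 2.34e-08). Igfbp3, a secreted target of p53, was at 200 ± 4.84 CPM against 932 ± 5.91 (-2.22 ± 0.13, adjusted p = 1.21e-10). Olig2 was lower at -1.63 ± 0.35 (adjusted p = 0.00103), but without giNPC P6 replicate 1 the change was -0.95 and not called, and without replicate 2 it was -2.98. In a fit of only these groups Olig2 had an adjusted p of 0.107.

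Y-linked genes also separated the lines, because Brain-NPC had nearly none. Kdm5d had 51.0 ± 45.4 CPM in giNPC P6, at least 245-fold higher (adjusted p = 2.61e-07), and Ddx3y and Uty had ratios of 771 (interval 138 to 30500) and 342 (interval 61.0 to 13600). In giNPC P6 replicates 1 and 2 Kdm5d had 18.9 and 83.1 CPM, Ddx3y 23.8 and 83.6, and Uty 8.32 and 39.1. The fitted log2 fold changes of Kdm5d, Ddx3y and Uty were 9.81, 7.99 and 6.48 without giNPC P6 replicate 2. Without replicate 1 they were 11.95, 9.80 and 8.71. Without Brain-NPC replicate 1 those of Ddx3y and Uty were 8.39 and 7.21, and without Brain-NPC replicate 2 they were 11.32 and 10.15. Eif2s3y had a ratio of 229 (interval 78.1 to 1110, adjusted p = 0.00213), but all its counts came from giNPC P6 replicate 2, and without that library the log2 fold change was -3.50 with an adjusted p of 0.763. The sex chromosome list had 4 of 5 genes higher (adjusted p = 0.000673, and adjusted p = 0.0755 with an estimated correlation).

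**Figure D3:**
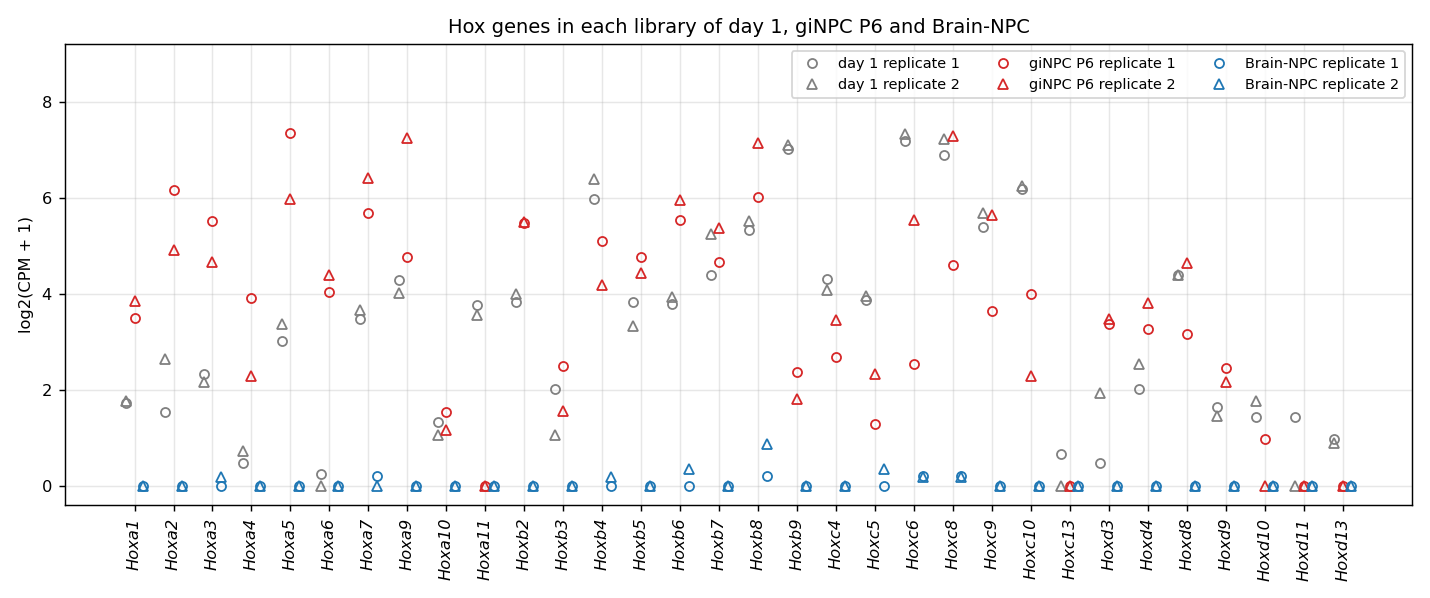
log2(CPM + 1) of 32 Hox genes in the libraries of day 1, giNPC P6 and Brain-NPC, 1 point per library. Brain-NPC lies near 0 for most genes, and 27 of the 32 were called higher in giNPC P6 than in Brain-NPC.

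In all, 1115 genes were higher and 1266 lower in giNPC P6 than in Brain-NPC, while 7169 genes differed from Brain-NPC at day 1, 4033 at day 21 and 4928 in pre-NPC. Of 32 Hox genes 27 were higher (median 8.64, or 6.01 with 20 genes at 0 in Brain-NPC or giNPC P6 set at their bound; camera adjusted p = 3e-26, and 0.000948 with an estimated correlation). Of 16 forebrain genes 8 were lower (median -2.09, bound -1.80, adjusted p = 0.00202, and 0.0431 with an estimated correlation). Of 12 midbrain and hindbrain genes 4 were higher (adjusted p = 0.0387, and adjusted p = 0.103 with an estimated correlation). Proliferation had 10 of 24 genes lower (median -0.95, adjusted p = 2.55e-10) and p53 and senescence 7 of 14 (median -1.14, adjusted p = 0.000666), at adjusted p = 0.00575 and 0.0235 with an estimated correlation. The neural progenitor list was not called, with 3 of 28 genes higher and 4 lower (adjusted p = 0.881), nor were the astrocyte list with 1 of 14 higher and 4 lower (0.41) and the oligodendrocyte lineage list with 6 of 18 lower (0.0658). There were 9 forebrain genes lower adjusted over the list alone, and the other counts were the same.

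The giNPC P6 line was also compared with day 1, the first sampled induction culture. These groups too may differ in the source of their cells as well as in stage. Sox2 was higher by 9.27 ± 0.24 (adjusted p = 1.71e-17) and Sall3, a zinc finger gene, had 403 ± 89.6 CPM against no counts, at least 1310-fold higher (adjusted p = 2.51e-15). Mmd2, Mt3, Timp4 and Agt, which led the rises by day 21, were at least 1860-fold, 1540-fold, 1310-fold and 1270-fold higher (adjusted p = 7.03e-17, 8.76e-13, 3.31e-14 and 2.07e-13). The fitted log2 fold change of Mt3, which lies beyond its bound, went from 14.42 to 13.64 without giNPC P6 replicate 2. Mmp10, a stromelysin, had 1410 ± 2.77 CPM at day 1 and no counts in giNPC P6, at least 6330-fold lower (adjusted p = 2.07e-16), and Grem1, Arhgdib, Ptgs2 and Tfpi2 were at least 2650-fold, 2500-fold, 2170-fold and 1530-fold lower (adjusted p = 6.48e-17, 2.58e-15, 2.25e-15 and 5.03e-16). Col6a1 fell from 3740 ± 51.3 to 7.71 ± 0.499 CPM (-8.91 ± 0.22, adjusted p = 1.71e-17) and Tgfb1 from 283 ± 3.11 to 1.57 ± 0.261 (-7.48 ± 0.26). Mdm2 fell (-3.25 ± 0.17), as did Cdkn2b, a cell cycle inhibitor (-3.75 ± 0.20). Meg3, an imprinted noncoding RNA, fell from 99.1 ± 2.68 to 0.480 ± 0.583 FPKM (-6.14 ± 0.20). Foxm1 rose by 2.41 ± 0.25, Aurkb by 2.35 ± 0.23, Ptch1 by 4.84 ± 0.30 and Id3 by 5.39 ± 0.41.

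In all, 3289 genes were higher and 2895 lower in giNPC P6 than at day 1. The fibroblast list had 28 of 29 genes lower and 1 higher (median -8.18, bound -8.15, camera adjusted p = 1.75e-17), the neural progenitor list 24 of 28 higher and 1 lower (median 8.65, bound 7.73, adjusted p = 1.88e-13), the smooth muscle list 9 of 9 lower (adjusted p = 3.55e-05), the astrocyte list 11 of 14 higher and 1 lower (adjusted p = 2.48e-05), the interferon list 16 of 19 lower (adjusted p = 1.08e-05) and the proliferation list 16 of 24 higher (adjusted p = 0.000203). These 6 calls held with an estimated correlation. Of 15 immune genes 14 were lower (adjusted p = 3.86e-09, and adjusted p = 0.11 with an estimated correlation), of 18 imprinted genes 12 were lower and 2 higher (adjusted p = 0.000766, and adjusted p = 0.0754 with an estimated correlation), and of 14 p53 and senescence genes 6 were lower and 1 higher (adjusted p = 0.0398, and adjusted p = 0.124 with an estimated correlation). The Hox list had 14 of 32 genes higher and 9 lower (adjusted p = 0.668), with a median of 0.45 and a mean of -0.06. There were 25 neural progenitor genes higher adjusted over the list alone, and the other counts were the same.

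Teratoma was compared with giNPC P6 to describe which tissue genes the tumour expressed. The labels do not give the source of the teratoma. The values below are therefore differences between groups and need not be changes of this line. Both giNPC P6 libraries held Y-linked transcripts, while teratoma had nearly none (below). Among the largest differences with higher values in teratoma were those of Dmbt1, Pnliprp1, Ctrb1, Reg3g and Ltf. Dmbt1, a mucosal glycoprotein, had 2350 ± 0.125 CPM and no counts in giNPC P6, at least 10600-fold higher (adjusted p = 1.15e-13). The pancreatic enzyme genes Pnliprp1 and Ctrb1 were at least 7470-fold and 6880-fold higher (adjusted p = 7.19e-14 and 1.66e-13), and Reg3g and Ltf at least 6920-fold and 4970-fold (adjusted p = 7.61e-13 and 3.11e-13). Genes of several tissues were present. Alb and Afp, liver genes, had 785 ± 17.6 and 148 ± 1.08 CPM, Krt5 and Krt19, keratins of stratified and simple epithelium, 226 ± 0.0355 and 625 ± 19.4, Acta1, skeletal muscle actin, 643 ± 6.76, and Cdh5, the endothelial cadherin, 155 ± 5.51, all with no counts in giNPC P6. Hbb-bs, adult beta-globin, had 586 ± 1.05 CPM. The neuron gene Tubb3 was at 557 ± 15.0 CPM in teratoma against 33.6 ± 6.27 in giNPC P6 (4.05 ± 0.20, adjusted p = 6.44e-13), and Syt1 at 138 ± 2.21 against 0.369 (8.46 ± 0.55). Mbp, which encodes myelin basic protein, was at 349 ± 5.18 FPKM against 0.769 ± 0.418 (7.65 ± 0.24).

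Progenitor genes were among those lower in teratoma. Sox2 was at 150 ± 3.3 CPM in teratoma against 766 ± 84.5 in giNPC P6 (-2.35 ± 0.15), and Olig1 at 59.6 ± 1.28 against 3420 ± 1400 (-5.84 ± 0.26, adjusted p = 1.23e-13). Map2 was at 49.0 ± 0.321 FPKM against 145 ± 20.8 (-1.54 ± 0.11, adjusted p = 7.13e-09). Ddx3y, Kdm5d and Uty, Y-linked genes, had no counts in teratoma and were at least 375-fold, 358-fold and 167-fold lower (adjusted p = 2.26e-09, 1.15e-08 and 2.42e-08). Their fitted log2 fold changes, which lie beyond these bounds, were -11.34, -11.26 and -10.16. They were -10.14, -9.81 and -8.63 without giNPC P6 replicate 2 and -11.96, -11.95 and -10.86 without replicate 1. Eif2s3y was lower as well, but without giNPC P6 replicate 2 its log2 fold change was 1.74 with an adjusted p of 0.831. Pou5f1, in contrast, was higher in teratoma, with a ratio of 19 (interval 5.02 to 161, adjusted p = 0.00557). That call was lost without giNPC P6 replicate 2.

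In all, 4599 genes were higher and 1503 lower in teratoma than in giNPC P6. Scaling mattered most here: the median log2 fold change of all genes was 0.038 with TMM and 0.225 with RLE size factors, a shift of 0.187, and the share of called genes that were higher went from 75.37% to 81.78%. No list median below changed sign with RLE. Epithelial genes were higher in 21 of 21 (median 10.17, bound 8.13, camera adjusted p = 1.16e-09), endoderm in 20 of 20 (median 9.73, bound 7.67, 1.16e-09), smooth muscle in 9 of 9 (2.14e-05), mesoderm and muscle in 13 of 14 (4.57e-06), surface ectoderm in 11 of 12 (4.96e-06), endothelial in 10 of 10 (7.58e-05), neuron in 17 of 19 with 1 lower (3.19e-05), fibroblast in 26 of 29 with 1 lower (4.89e-09), interferon response in 16 of 19 (2.09e-05) and imprinted in 14 of 18 (0.000163). Proliferation genes were lower in 24 of 24 (median -1.88, 4.22e-12), neural progenitor in 26 of 28 with 1 higher (median -2.74, 1.68e-10) and Hox in 22 of 32 with 4 higher (median -2.40, 2.21e-05). These 13 calls held with an estimated correlation, at adjusted p of 0.0474 or less. The calls of 7 lists did not hold: immune (15 of 15 higher, 2.46e-08, and adjusted p = 0.128 with an estimated correlation), erythroid (3 of 3 higher, 0.00203 and 0.0936), pluripotency (11 of 15 higher and 2 lower, 0.0225 and 0.17), forebrain (12 of 16 higher and 1 lower, 0.0112 and 0.0853), oligodendrocyte lineage (13 of 18 higher and 1 lower, 0.0225 and 0.0936), glycolysis (6 of 16 lower and 2 higher, 0.0199 and 0.469) and sex chromosome (5 of 5 lower, 0.00638 and 0.139). The midbrain and hindbrain list, with 5 of 12 genes higher and 4 lower, was not called (0.925), and its median of 0.25 and mean of 2.03 were positive while camera ranked it down. All these counts were the same adjusted over the list alone.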

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

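With 2 libraries per group, spread was estimated over all groups, and leaving a library out leaves 1 in its group, which is then taken to vary like the others. DESeq2 left 580 of 596 results of named genes as they were and weakened 16, and RLE left 595 and weakened 1. Log2(FPKM + 1) weakened 33, the same without a filter 40, log2(FPKM + 0.1) 13, only the groups of the comparison 13, no filter 3 and no teratoma libraries 4, and leaving out each library in turn weakened 88 and left 13006. RLE moved the median of teratoma against giNPC P6 over all genes from 0.038 to 0.225. The labels do not say whether libraries with the same replicate number share an origin. The differences of replicate 1 minus replicate 2 were correlated across genes between groups. Over 55 pairs of groups this correlation had a median of 0.005 (-0.127 to 0.1), which cannot exclude a shared origin. A block for the number left counts of calls at 0.96 to 1.03 times and weakened 3 results of named genes.

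Only the groups of the comparison gave 917 genes lower in giNPC P6 than in pre-NPC, and 85, 177, 233 and 397 transiently high at days 14, 17 and 21 and in pre-NPC. With no fold minimum 880, 1604, 2201, 2773 and 3460 genes were lower at days 4, 7, 10, 14 and 21 than at day 1. Pre-NPC then had 2088 higher and 2271 lower than day 21, giNPC P6 2057 and 2513 against pre-NPC and 2100 and 2436 against Brain-NPC. Teratoma had 3643 lower, 6306 differed between day 21 and Brain-NPC, and 490, 567 and 952 were transient at days 17 and 21 and in pre-NPC.

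On log2(FPKM + 1), 134, 298, 411 and 1095 genes were lower at days 4, 7, 10 and 14, 643 higher in pre-NPC than at day 21, 926 lower in giNPC P6 than in pre-NPC, 735 higher than in Brain-NPC, and 941 lower in teratoma. Unfiltered these were 133, 296, 409, 1095, 641, 919, 723 and 941. On log2(FPKM + 0.1), day 10 had 3585 higher and 567 lower, day 14 3634 higher, pre-NPC 2041 lower, and 1075, 408, 529 and 656 were transient at days 10, 14, 17 and 21. Without genes following the immune list 476 and 323 were transient at days 7 and 10. Of 403 list tests 113 were called, 68 with an estimated correlation and 288 by fry.

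Among the genes reported here, the direction turned for Postn in pre-NPC against day 21 (0.33 on counts, adjusted p = 0.97, and -3.30, -3.44 and -3.30 on log2(FPKM + 1), log2(FPKM + 0.1) and unfiltered). Tsix, at 0.00 on unfiltered log2(FPKM + 1), had no clear direction there. Fry turned the p53 list at day 7 (0.25) and the midbrain and hindbrain list in teratoma (2.03). Without giNPC P6 replicate 2, Eif2s3y was at -3.50 in giNPC P6 against Brain-NPC and 1.74 in teratoma against giNPC P6, and it was at 11.12 without Brain-NPC replicate 2 and -11.09 without teratoma replicate 2. The transient count of day 14 was 112 without day 1 replicate 1 and 201 without giNPC P6 replicate 2.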

Other observations

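Genes of these first paragraphs were chosen after their values were seen. Some smooth muscle genes had a separate peak at day 21: Acta2 stood at 108 ± 12.1 CPM at day 1, 10.6 ± 1.63 at day 17, 382 ± 31.0 at day 21 (log2 fold change against day 1 1.82 ± 0.22, adjusted p = 4.32e-07) and 7.26 ± 2.72 in pre-NPC. Tagln went from 13.3 ± 2.85 CPM at day 17 to 348 ± 44.9 at day 21 and was at 9.65 ± 4.70 in pre-NPC. Of 9 tested smooth muscle genes 4 (Acta2, Des, Myl9 and Tagln) were transiently high at day 21 (Fisher's exact test, adjusted p = 0.00096), while 2 of the 9 were lower at day 21 than at day 1 and the list was not called there (camera adjusted p = 0.737).

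The immediate early genes Fos and Egr1 were highest at day 17. Fos was at 19.5 ± 2.72 CPM at day 1, 2510 ± 13.5 at day 17 (7.01 ± 0.27, adjusted p = 4.81e-15) and 70.7 ± 6.21 at day 21, and Egr1 was at 237 ± 0.780, 3070 ± 303 (3.69 ± 0.16, adjusted p = 2.1e-14) and 266 ± 33.7. Of 15 tested genes of the list 5 (Egr1, Fos, Fosb, Ier2 and Junb) were transiently high at day 17 (Fisher's exact test, adjusted p = 0.000252), and 5 (Atf3, Fos, Fosb, Hmox1 and Junb) at day 7 (adjusted p = 0.0223). Id1 was also highest at day 17 among the sampled days, at 165 ± 34.6 CPM against 6.03 ± 3.93 at day 1 (4.75 ± 0.42, adjusted p = 3.44e-09). The imprinted H19 was at 9120 ± 1710 CPM at day 7 against 1570 ± 126 at day 1 (2.54 ± 0.28, adjusted p = 4.27e-07). It held the most counts of any gene in both day 10 libraries (0.84% and 0.89%), so days 7 and 10 were not ranked. H19 was at 200 ± 4.97 at day 17, 7.03 ± 6.80 in giNPC P6 and 2770 ± 48.9 in teratoma.

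Of the tests below, that of RLE size factors was planned, and all others were chosen only after the result was seen. Macrophage and interferon-response transcripts were high from day 4 to day 10. Macrophages in the cultures are a possible explanation, since 30 of 35 tested further macrophage markers were higher at day 7 than at day 1. From day 1 to day 4 the median log2 fold change of the interferon genes lay 1.13 above that of the macrophage genes (95% interval 0.51 to 1.46). To day 10 it lay 1.13 above (0.58 to 1.51), and to day 7 0.31 above (-0.31 to 1.35). The intervals in this paragraph resample the genes of each list. They take genes as independent and leave out the spread between libraries. At days 4 and 10 these values argue against interferon genes rising only with macrophage number, if the macrophage genes come from macrophages alone. That condition was not tested, and 4 of the further markers had at least 10 CPM in giNPC P6. Day 7 is left open. Library scaling, which moves every gene of a library alike, is an unlikely cause, as the immune median at day 7 lay 3.23 (2.52 to 3.51) above that of all tested genes; RLE size factors moved the day 7 median of all genes by only 0.009 and so tested nothing here.

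Hox genes were high in giNPC P6 and near 0 in Brain-NPC. Fibroblasts left in the culture are an unlikely explanation, because the median log2 fold change from day 1 to giNPC P6 was 1.07 over the 27 Hox genes higher in giNPC P6 than in Brain-NPC, 0.45 over all 32 tested Hox genes and -8.18 over 29 fibroblast genes. Counts lost in genes with several transcripts are unlikely as well, with 25 Hox genes higher in giNPC P6 on log2(FPKM + 1). No biological explanation was tested.

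Xist occurred together with Y-linked transcripts in pre-NPC (384 and 610 CPM of Xist) and giNPC P6 (643 and 22.4 CPM), while Xist was at most 1.39 CPM from day 1 to day 21. A mixture of female and male cells could give this. As fractions of their mean at days 1 to 21, the Y-linked genes of 2 of the 4 libraries lay more than 4-fold apart. So did those of 2 of the 14 libraries of days 1 to 21. The lowest gene differed: Eif2s3y in pre-NPC replicate 1 and giNPC P6 replicate 1 (0.0264 and 0), Ddx3y in both day 17 libraries (0.0521 and 0.0928). Pre-NPC also had more Xist than Brain-NPC (335 and 337 CPM), at median Y-linked fractions of 0.853 and 0.638. Xist expressed in male cells could also give it, and the lowest median Y-linked fraction of the 4 libraries was 0.151, in a giNPC P6 library. The tests left both open.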
